A study of Homo sapiens with 2 samples.

How the data were processed

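RNA of 2 AsPC-1 cultures, 1 uncompressed and 1 compressed at 2.9 mmHg for 24 h, was measured on 2 GeneChip Human Gene 2.0 ST arrays, per the labels. The deposited values are on a log2 scale, which the authors made with RMA and the Transcriptome Analysis Console, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays by quantile normalization and summarises the probes of each probe set. It therefore removes a change shared by all genes and compresses changes near background. Tool versions, library files and the genome build are not given in the sources used here. The table held 1 value per array for each of 53617 probe sets, from 0.162 to 13.3 on the uncompressed and from 0.289 to 13.2 on the compressed array. The sorted values of the arrays differed by 0.0276 on average and by 0.213 at most. Exactly equal values on both arrays were found for 3118 probe sets (5.82%) and for 182 of the kept genes. No detection calls and no scanner intensities were used here, so whether a dim probe set was above background is unknown. Group labels came from the treatment characteristic of each sample. Both arrays are the single sample of their group, so the files allow no estimate of the spread between cultures.

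Gene names came from the platform annotation, which paired 16098 probe sets with 1 gene each and 0 with several. All 16098 gene identifiers were found in the NCBI RefSeq gene table (GRCh38.p14), which gave the current symbol and biotype. The other 37519 probe sets are unnamed here, and no coordinates are given because the build of the array files is not stated. Of the 14884 genes, 779 had more than 1 probe set, and the probe set with the highest mean over both arrays was used. Genes were kept where that mean was at or above the median over genes, 4.79, which left 7442 genes, 6876 of them protein-coding.

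With 1 array per group no test was made. The difference compressed minus uncompressed was computed per gene, and genes were counted at a fixed size of 1.5-fold, which is 0.58 on the log2 scale. A set of 42 gene lists (zinc handling, mechanical, growth and stress signalling, metabolism, proliferation, cell state and markers of other cell types) was written down before the data were examined, as were the size rule, the filter, most alternatives and the rule for naming genes. Each list with at least 5 kept genes was summarised by its median difference and by that median's percentile among 10000 random lists of the same size matched on mean level in 20 bins. A list was set apart where the percentile was below 0.5 or above 99.5. Members without a named probe set could not count, so a list's values describe its named and kept members, not a whole pathway. The result of 1 list is not reported here. This percentile describes these 2 arrays and is not a p-value. Genes named in the text are the 15 with the largest positive and the 15 with the largest negative difference among kept genes other than small, non-coding or uncharacterised RNAs by symbol pattern, up to 3 members in each direction of each list, the metallothioneins and zinc transporters, and 8 fixed genes (ACTB, CDH1 and CCN1 of these had no named probe set here). Any other gene is named as a further member of a list described or is said to have been chosen after its values were seen.

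The size rule and the list percentile were tested on simulated data for this comparison, on 7442 genes with a noise SD of 0.248. The rule found 48 of 50 genes made 2-fold higher, 49 of 50 made 2-fold lower, 50 of 50 at 3-fold in each direction and 108 of 7242 unchanged genes. Of 200 unshifted lists of 12 genes, 0 were set apart, and of 200 lists shifted by 0.25, 114 were. The simulated noise was independent between genes and of the same SD at all levels. That SD came from the spread of the measured differences, not from replicates. Real genes of a list can vary together, so these counts are not the error rates of the rule or the percentile in these data.

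The alternatives were no level filter, a filter at the 75th percentile, the mean of all probe sets of a gene, a loess correction of the difference against mean level (span 0.3), centring on the median, repeated quantile normalization over the named probe sets, leaving out non-coding symbols, sizes of 2-fold and 1.25-fold, and the mean in place of the median. Lists of glucocorticoid-induced genes, enterocyte brush-border genes and LXR targets were added after the data were seen and before their own values were. Counting identical values once, protein-coding genes alone, a filter on the brighter of the 2 arrays and the repeated quantile normalization of named genes were added after the data were seen. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.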

Results

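Gene expression was measured in AsPC-1, an established human pancreatic adenocarcinoma line, grown as a 3-dimensional culture under a collagen gel overlay. The cells of 1 culture were left uncompressed and those of the other were kept under a compressive stress of 2.9 mmHg, both for 24 h. Total RNA of each was hybridised to 1 GeneChip Human Gene 2.0 ST array, a whole-transcript array that reports a level per probe set. The deposited levels are log2 RMA signals for 53617 probe sets, of which 16098 carried the name of 1 gene, giving 14884 genes. The uncompressed array had a median of 3.75 and the compressed array a median of 3.72 over all probe sets, and the Pearson correlation between the arrays was 0.978 across all probe sets and 0.972 across the 7442 genes kept at or above the median gene level of 4.79. With 1 array per condition no difference below has a replicate check, no test and no p-value can be given, and the number of arrays limits the precision. Differences are therefore described by size, as compressed minus uncompressed on the log2 scale, and "higher" and "lower" refer to these 2 arrays.

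The comparison of compressed with uncompressed cells addressed the transcriptional response of pancreatic cancer cells to compression. The compressed culture had higher levels of metallothioneins, of cholesterol biosynthesis genes and of immediate-early genes as groups, and lower levels of G2/M and DNA replication genes. In all, 294 kept genes were at least 1.5-fold higher in the compressed culture and 83 were at least 1.5-fold lower, which are 3.95% and 1.12% of the kept genes. At a size of 2-fold, 71 genes were higher and 6 were lower. With no level filter, 560 of 14884 genes were higher and 421 lower by 1.5-fold. The interquartile range of the difference over kept genes ran from -0.15 to 0.18 around a median of 0.01, which corresponds to a robust SD of 0.248 across genes. Where a protein-coding gene had exactly 2 different probe sets above the level floor (150 genes), the difference between these probe sets gave an SD of 0.184 for a single probe set's difference. Among the 7 of these genes whose brighter probe set passed 1.5-fold, the other probe set had the same direction in 6 and passed 1.5-fold in 0.

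**Figure D1:**
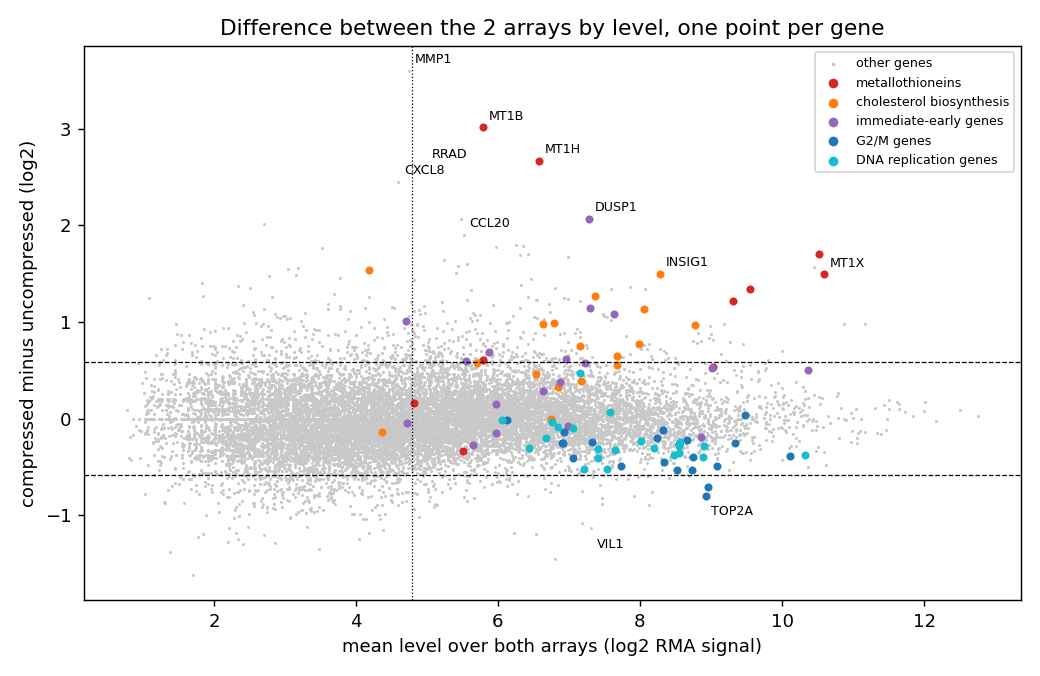
Each point is 1 gene, with its mean level over the 2 arrays (log2 RMA signal) on the x axis and the difference compressed minus uncompressed (log2) on the y axis; dashed lines mark 1.5-fold, the dotted line marks the level floor of 4.79, and colours mark the members of 5 gene lists. The metallothioneins MT1B and MT1H lie at 3.01 and 2.67, and the G2/M and DNA replication genes lie mostly below 0. MT1B was below the floor in the uncompressed culture (4.28), so the size of its difference is uncertain.

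Among kept genes other than small, non-coding or uncharacterised RNAs, the 15 largest positive differences included 4 metallothionein sequences. MT1H was 6.37-fold higher (log2 level 5.25 in the uncompressed and 7.92 in the compressed culture). DUSP1, a phosphatase that inactivates MAP kinases, was 4.19-fold higher (6.25 and 8.31). The metallothionein pseudogene MT1L was 3.48-fold higher, the immediate-early gene ARC 3.46-fold, THBS1, which encodes the matrix glycoprotein thrombospondin-1, 3.27-fold, and MT1G 3.26-fold. SAT1, the polyamine acetyltransferase, was 3.25-fold higher, and IGFBP1, a secreted insulin-like growth factor binding protein, 3.08-fold (8.01 and 9.63). USP17L12 and USP17L9P, near-identical multicopy sequences, carried the same values on both arrays (4.76 and 6.37), and a second probe set of USP17L9P brought its mean difference to 0.15. The others were MT1B (4.28 and 7.30), RRAD, which encodes a Ras-related GTPase (3.68 and 6.30), the keratin-associated protein gene KRTAP2-3 (4.45 and 6.51), the chemokine gene CCL20 (4.57 and 6.48) and EID3 (4.42 and 6.06). These 5 and the USP17 sequences lay below the floor of 4.79 in the uncompressed culture. Whether they were above background there is unknown, so no fold is given. MMP1, the interstitial collagenase, read 2.95 in the uncompressed and 6.55 in the compressed culture, with a mean of 4.75 just under the floor, so it is in none of the counts of kept genes. It was singled out after its values were seen, and the uncompressed level is not known to be above background, so no fold is given.

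The largest negative differences were smaller in size. ANXA13, an annexin of intestinal epithelium, was 2.28-fold lower (7.13 in the uncompressed and 5.94 in the compressed culture), and GRAMD1B, which encodes a sterol transfer protein, was 2.26-fold lower. VIL1, which encodes the microvillus protein villin, was 2.20-fold lower (7.88 and 6.74), and GPA33, an intestinal cell surface antigen, 2.11-fold lower (7.72 and 6.64). The zinc finger gene ZNF100 read 5.40 in the uncompressed and 4.39 in the compressed culture. The others of the 15 largest negative differences were GALM, TPSAB1, TM4SF4, CLRN3, TMCO4, SEC14L4, LONRF2, TLCD2, ZNF480 and IRF8, with differences between -0.91 and -0.80. In the compressed culture ZNF100, GALM, TPSAB1, TMCO4 and ZNF480 lay below the floor, so the sizes of their differences are uncertain.

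Metallothioneins, small cysteine-rich proteins that bind zinc and copper, were listed because the study's title places intracellular free zinc in the response to compression. Of the 10 named and kept members, 7 were at least 1.5-fold higher and 0 lower, and their median difference was 1.28 (2.43-fold). All 7 named MT1 genes of the list were among the higher ones, and MT1A had no named probe set here. MT1X and MT1G were 2.82-fold and 3.26-fold higher, at compressed levels of 11.34 and 11.38. MT1M and MT1F were 2.53-fold and 2.33-fold higher, and MT1E 1.53-fold, under the rule after loess correction (difference 0.58) and repeated quantile normalization (0.55). MT2A differed by 0.54, MT3 by 0.16 and MT4 by -0.34. The list's median was above those of all 10000 random lists matched on level, whose central 95% lay between -0.15 and 0.19. The MT1 genes are near-identical paralogs whose probes may share targets, so the division of the signal among them is uncertain. No named probe set was available here for any member of the SLC30 and SLC39 families of zinc transporters, which were not analysed here.

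**Figure D2:**
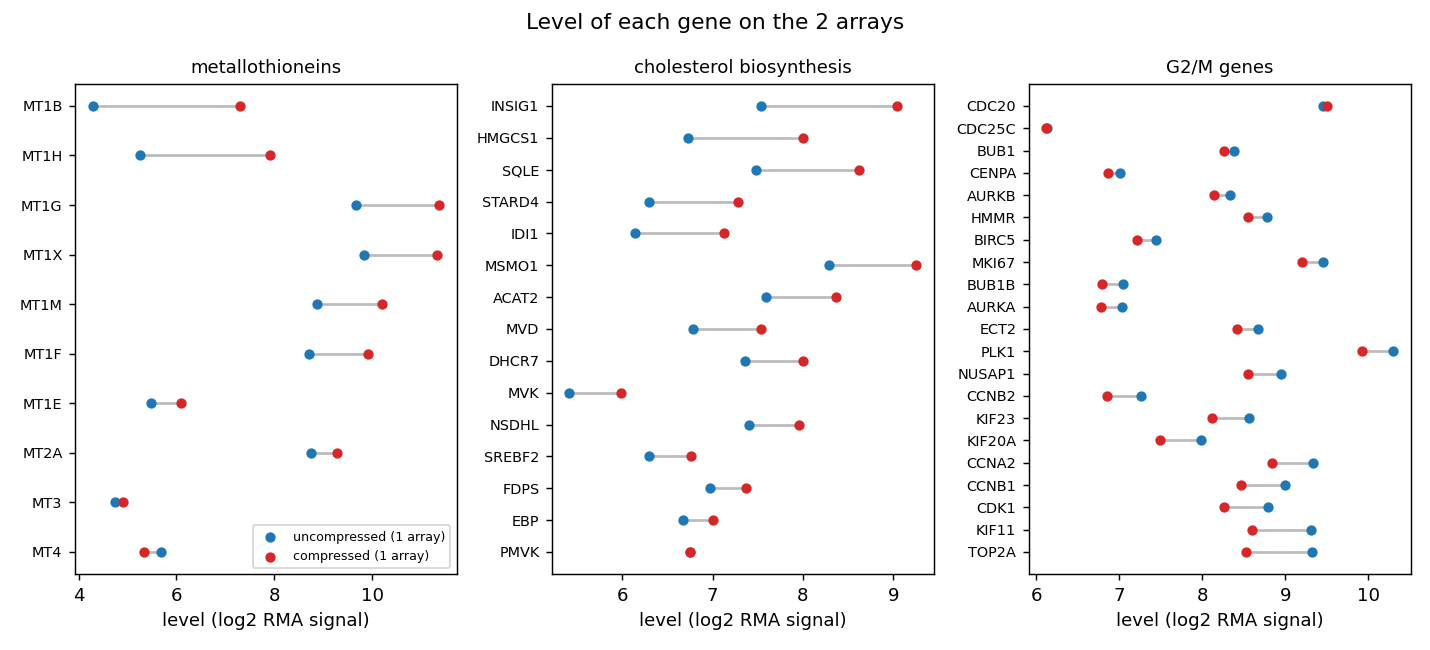
Level (log2 RMA signal, x axis) of each kept member of 3 gene lists on the uncompressed array (blue) and on the compressed array (red), 1 array each, with no error bars since there are no replicates. The 7 MT1 genes and 14 of the 15 cholesterol genes are higher in the compressed culture, and 20 of the 21 G2/M genes are lower, with CDC20 at 0.04 (just below 0 after repeated quantile normalization).

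Genes of cholesterol biosynthesis and its regulation were higher as a group. Of 15 kept members, 9 were at least 1.5-fold higher, 0 were lower, and 14 had a positive difference, with PMVK at 0.00. The median difference was 0.75 (1.68-fold), above the medians of all 10000 random lists. INSIG1, a sterol-regulated inhibitor of SREBP processing, was 2.83-fold higher (7.54 and 9.04), HMGCS1, the cytosolic HMG-CoA synthase, 2.41-fold, and SQLE, squalene epoxidase, 2.20-fold (7.48 and 8.62). EBP differed by 0.33 and FDPS by 0.39. In the fatty acid synthesis list, 2 of 9 kept genes passed 1.5-fold: ACSS2, the cytosolic acetyl-CoA synthetase, was 2.36-fold higher and SCD, stearoyl-CoA desaturase, 1.53-fold (under the rule with the mean of its probe sets, 0.54), while FASN differed by 0.39 and ACLY by -0.06. That list's median of 0.19 was at the 95.2nd percentile of its random lists.

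Immediate-early genes were also higher as a group, and single genes of EGFR and ERK signalling passed 1.5-fold. Of 16 kept immediate-early genes, 6 were at least 1.5-fold higher and 0 lower, with a median of 0.51 above those of all random lists. Besides DUSP1, the transcription factor genes EGR1 and KLF6 were 2.21-fold and 2.11-fold higher, and the AP-1 genes FOS, JUND and FOSB 1.61-fold, 1.54-fold and 1.51-fold. A second probe set of EGR1 differed by 1.24, that of FOS by 0.44 and that of FOSB by 0.12, and with the mean of the probe sets FOS (0.56) and FOSB (0.36) did not pass. After repeated quantile normalization JUND (0.57) did not pass either. KLF4 differed by -0.27, MYC by -0.19 and JUN by -0.15. In the list of EGFR ligands and receptors, which also holds the regulators ERRFI1 and LRIG1, 3 of 6 kept genes passed. ERRFI1, a feedback inhibitor of EGFR, was 1.98-fold higher, EGFR itself 1.76-fold (8.62 and 9.44) and the ligand gene HBEGF 1.67-fold. EREG differed by 0.57 and LRIG1 by -0.07. The median of these 6 genes, 0.65, was at the 99.99th percentile, but with no level filter the median of 10 genes was 0.10, at the 89.29th percentile. Of 10 kept ERK feedback genes, 1 passed, SPRY4 at 1.64-fold, and the median of 0.38 was at the 99.99th percentile, against 0.23 with no level filter. Without IER3 and FOSL1, which are also in the immediate-early list, the median of 8 genes was 0.23, at the 97.92nd percentile, a subset chosen after the values were seen.

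Proliferation genes were lower by small amounts shared across nearly all members. Of 21 kept G2/M genes, 20 had a negative difference, 2 were at least 1.5-fold lower, and the median was -0.26. TOP2A, topoisomerase II alpha, was 1.74-fold lower (9.32 and 8.52) and the mitotic kinesin gene KIF11 1.63-fold lower (9.31 and 8.60). CDK1 and CCNB1 each differed by -0.53, MKI67 by -0.25, and CDC20, the 1 positive member, by 0.04, which was just below 0 after repeated quantile normalization. Of 22 kept DNA replication genes, 20 had a negative difference and 0 passed 1.5-fold in either direction, with a median of -0.29. MCM2 and GINS1 each differed by -0.52 and CDT1 by -0.41, whereas the G1/S cyclin gene CCNE1 differed by 0.47. Both medians were below those of all 10000 random lists.

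**Figure D3:**
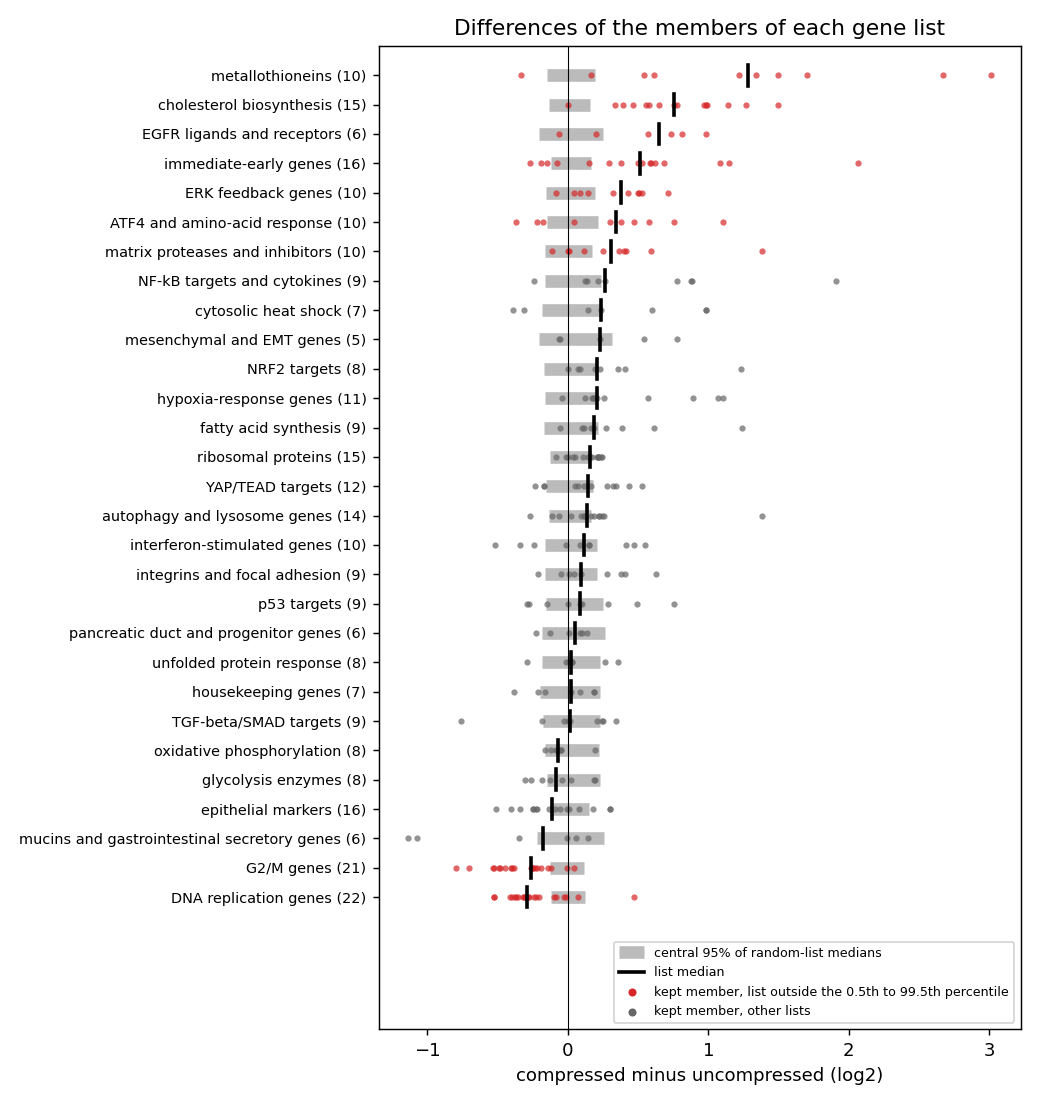
Difference compressed minus uncompressed (log2, x axis) of each kept member (points) of 29 gene lists with at least 5 kept genes (number in brackets), with the list median (black bar) and the central 95% of the medians of 10000 random lists matched on level (grey band). Red marks the 9 lists whose median lies among the lowest or highest 0.5% of the random medians, 7 above and 2 below.

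Of the 42 lists, 30 had at least 5 kept genes, and the medians of 9 lay among the lowest or highest 0.5% of their random medians. Some lists share genes, and genes of a list can vary together between single cultures, so this number cannot be set against chance. The summary values of 23 of the 30 lists moved by over 1.5 times or changed sign under at least 1 alternative. The mean in place of the median was counted as an alternative. Of the 9 lists, those not yet described were the ATF4 and amino-acid response and the matrix proteases and inhibitors. In the ATF4 list (10 kept, median 0.34, 99.8th percentile), 2 genes passed, DDIT4, an inhibitor of mTORC1 signalling, at 2.15-fold higher, and SESN2, a stress-induced sestrin, at 1.69-fold. ATF4 itself differed by 0.47, and the serine synthesis and one-carbon enzyme genes PSAT1 and SHMT2 by -0.37 and -0.18. This list's median moved to the 94.2nd percentile under a stricter level filter, and its mean was at the 98.83rd. In the protease list (10 kept, median 0.31, 99.9th percentile), 2 genes passed: CTSL, the lysosomal protease cathepsin L, was 2.61-fold higher and TIMP2, an inhibitor of metalloproteinases, 1.51-fold (just under the rule after repeated quantile normalization). MMP14 and MMP15 differed by 0.00 and 0.01.

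Several lists held single genes with large differences while their medians were not among the lowest or highest 0.5% of random medians. In the NF-kB and cytokine list (9 kept, median 0.27, 98.7th percentile), 4 genes were at least 1.5-fold higher: CCL20, NFKB2 at 1.85-fold, the cytokine gene LIF at 1.84-fold and CXCL5 at 1.71-fold. CXCL8, under the level floor and singled out after its values were seen, read 3.37 in the uncompressed and 5.82 in the compressed culture. In the hypoxia list (11 kept, median 0.21, 98.0th percentile), 3 passed: DDIT4, NDRG1 at 2.10-fold and the mitophagy receptor gene BNIP3L at 1.85-fold, while VEGFA differed by 0.21 and LDHA by -0.04. In the cytosolic heat shock list (7 kept, median 0.24, 97.4th percentile), 3 passed. HSPA1A and HSPA1B, near-identical genes that their probes may not separate, were 1.98-fold higher each. The co-chaperone gene BAG3 was 1.51-fold higher, but under the rule after loess correction (0.57) and repeated quantile normalization (0.53). HSPD1, at -0.31, was in this list although it encodes a mitochondrial chaperonin. The list's median was 0.14 after repeated quantile normalization. Of the NRF2 targets (8 kept, median 0.21, 97.53rd percentile; mean 0.32), HMOX1, heme oxygenase 1, was 2.35-fold higher and the other 7 differed by less than 1.5-fold. In the mucin and gastrointestinal list (6 kept, median -0.18, 5.45th percentile), VIL1 and GPA33 were lower and CEACAM6 differed by -0.01. None of the mucin genes of this list had a named probe set here, so its values describe the other members. Summarised by the mean in place of the median, the NF-kB (0.55), hypoxia (0.43), fatty acid (0.34) and mucin and gastrointestinal (-0.39) lists were among the highest or lowest 0.5%. The NF-kB list was so too by its median with no level filter (0.24) and with a filter on the brighter array (0.52), the latter added after the data were seen.

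Lists tied to mechanical signalling and cell state showed small differences. Of 12 kept YAP/TEAD targets, 0 passed 1.5-fold, with IGFBP3 at 0.53, AXL at 0.43 and CCN2 at 0.34 (median 0.14, 94.2nd percentile). With the mean of all probe sets CCN2 was at 0.17 and the list's median at 0.07. The 9 kept integrin and focal adhesion genes had a median of 0.09, which was 0.03 after repeated quantile normalization, and a mean of 0.17. Among them CAVIN1, a caveolar coat gene, was 1.54-fold higher, and PXN and VCL differed by 0.40 and 0.37. PIEZO1, a mechanically gated cation channel gene, was 1.54-fold higher (6.49 and 7.12), as 1 of 4 kept channel genes, and did not pass after repeated quantile normalization (0.58). Of 5 kept mesenchymal genes (median 0.23, but 0.04 over all 13 named genes with no level filter), the transcription factor gene ZEB1 was 1.71-fold higher, SNAI2 differed by 0.54 and VIM by 0.23. SNAI1 was below the floor on both arrays (4.12 and 4.53). Of 16 kept epithelial markers, 0 passed, and 11 had a negative difference, with ST14 at -0.51, ESRP1 at -0.40 and EPCAM at -0.34 (median -0.11, 3.45th percentile). After repeated quantile normalization EPCAM was at -0.53 and the median at -0.20. Of 9 kept TGF-beta and SMAD targets (median 0.01, just below 0 after repeated quantile normalization), BAMBI, a BMP and activin decoy receptor gene, was 1.69-fold lower.

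The remaining lists with 5 or more kept genes had medians between -0.08 and 0.16, none among the lowest or highest 0.5%. These medians were 0.16 for ribosomal proteins, 0.14 for autophagy and lysosome genes, 0.12 for interferon-stimulated genes, 0.09 for p53 targets, 0.05 for pancreatic duct and progenitor genes, 0.02 for the unfolded protein response, 0.02 for housekeeping genes, -0.07 for oxidative phosphorylation and -0.08 for glycolysis enzymes. Under the alternatives these values ranged from 0.07 to 0.17 for ribosomal proteins, 0.09 to 0.18 for autophagy, -0.0043 to 0.15 for interferon-stimulated genes, 0.0092 to 0.11 for p53 targets, -0.08 to 0.09 for duct genes, -0.0019 to 0.05 for the unfolded protein response, -0.04 to 0.02 for housekeeping genes, -0.13 to -0.05 for oxidative phosphorylation and -0.19 to -0.04 for glycolysis. The interferon, duct, unfolded protein and housekeeping values thus have no settled sign. Members without a named probe set are missing, so the medians cover only part of each list. Named were 8 of 24 oxidative phosphorylation genes, all of them UQCRC, CYC1 or COX genes. Of the unfolded protein response genes 9 of 20 were named, without HSPA5, and of the glycolysis enzymes 9 of 18. The probe set named GAPDH differed by 0.19, and by 0.11 after repeated quantile normalization. In these lists CTSL and SESN2 alone passed 1.5-fold. Of the markers of other cell types, 10 were kept: 1 acinar, 2 endocrine, 3 fibroblast, 2 endothelial and 2 leukocyte. CD68, a lysosomal glycoprotein gene also used as a macrophage marker, was the 1 past 1.5-fold, at 1.75-fold higher (8.45 and 9.26). The fibroblast marker LUM differed by -0.36 and the leukocyte marker LYZ by -0.22. Of 4 kept squamous keratinocyte genes and 3 kept antigen presentation genes, 0 passed, with KRT80 at 0.45 and TAPBP at 0.33. Collagen genes and replication-dependent histones had no named probe set here and were not analysed.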

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

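The tests of an offset, of shared probes and of variation between cultures, and the count with identical values taken once, were chosen after the data were seen; the other tests below were written down before their results were seen. Probe sets without a gene name here, which no comparison used, also differed between the arrays. Of 8981 such probe sets above the level floor of 4.79, 252 were at least 2-fold higher and 56 at least 2-fold lower in the compressed culture. Probe set 17118614 was 10.6-fold higher (6.33 and 9.74) and probe set 17079432 read 6.54 in the uncompressed culture and 4.10, below the floor, in the compressed culture.

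The metallothioneins formed the list with the largest median difference, 1.28. A trend of the difference with signal level was argued against, since the loess-corrected median was 1.29 and still above all 10000 random lists. Probes shared between near-identical MT1 genes stay open: 3 members exceeded the difference of MT1X, the brightest, but MT1X reached 11.34, where signal can be compressed. A difference in glucocorticoid exposure, which can also raise metallothioneins, stays open too, because only 2 of the genes of an added glucocorticoid-induced list were kept (FKBP5 at -0.23 and PER1 at 0.17, median -0.026). A response to intracellular zinc may fit the pattern but was not tested, as the zinc transporter genes were not analysed here.

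The G2/M and DNA replication genes together (43 kept, 40 of them negative) had a median difference of -0.29. A level trend was argued against, since the median was -0.28 after loess correction, below all random lists. An offset shared by all genes was argued against as well, since the joint list lay below all random lists, which such an offset would move too. The median of all kept genes, 0.007, is no evidence here, because the deposited values were already quantile-normalized. Repeated quantile normalization, which moved other genes, left the joint list at -0.31, below all random lists. An offset confined to some genes was not tested. Variation between single cultures, such as a difference in density or growth state, cannot be told apart from an effect of compression, because the measured median of -0.29 comes from 1 array per group. Compression, the difference that the design names, stays among the open explanations, untested.

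More genes were higher than lower, 294 against 83, a ratio of 3.54. A level trend was argued against as its whole cause (3.08 after loess correction). Genes with the same pair of values were too few to produce it: counting each pair once left 7433 of 7442 genes and a ratio of 3.53. Related genes that may share probes but differ in level, such as HSPA1A and HSPA1B, were not covered by that count. An offset between the arrays stays open for part of the asymmetry: centring gave 3.30 but moved genes by only 0.007. Repeated quantile normalization, which moved values more, lowered the ratio to 2.25 (239 and 106). The asymmetry was smaller with no level filter, at 560 and 421. An effect of compression stays open and untested, with 1 array per group.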

How the results depend on the processing

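Counts of genes moved with the level filter and with the size rule. With no filter 560 genes were higher and 421 lower, with the stricter filter 137 and 30, at 2-fold 71 and 6, and at the smaller size rule 1005 and 616, because these settings test or pass other numbers of genes by construction. Under the scaling, probe set, symbol, protein-coding and identical-value alternatives and the brighter-array filter (the last 3 chosen after seeing the data), the counts stayed within 1.5 times, from 239 to 343 higher and from 67 to 113 lower. The repeated quantile normalization gave 239 and 106, and shifted the median of kept genes by -0.04, the largest shift of the 3 scalings. Of 322 list summaries recomputed, means included, 313 kept their side of the percentile limits and 0 of those outside the limits changed sign. The lists that lost their place were EGFR ligands and receptors with no filter (0.10) and the ATF4 list with the stricter filter (0.21) and by its mean (0.29). Lists that passed a limit by the mean were hypoxia (0.43), fatty acid synthesis (0.34) and the mucin and gastrointestinal list (-0.39), which held no measured mucin gene. The NF-kB targets passed by the mean (0.55), with no filter (0.24) and with the brighter-array filter (0.52). For these lists the cause was not tested. Of 744 differences of 248 genes recomputed, 743 moved by less than 0.248, the robust SD across genes, USP17L9P moved to 0.15 with the mean of its probe sets, and 0 of those past 1.5-fold changed sign. Of 79 of these genes past 1.5-fold, 10 fell under it in at least 1 alternative, 4 with loess correction, 4 with the mean of probe sets and 8 with repeated quantile normalization. The count of 743 is no measure of robustness. Most of the 248 genes had 1 probe set, which the mean of probe sets cannot move. Loess correction and repeated quantile normalization shifted the median of kept genes by only -0.006 and -0.04. No replicate could be left out and no paired analysis was possible because each group has 1 array. Depth does not apply to arrays, and signal over background is unknown.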

Other observations

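The values by RNA class, the genes under the level floor and the genes named with them were chosen after the data were seen, and the tests of the 2 added lists were written down before their results were seen. Long non-coding RNAs past 1.5-fold were all higher: of 209 kept, 18 were higher and 0 lower. Of 6876 protein-coding genes 247 were higher and 67 lower, that is 3.59% higher against 8.61%, a contrast that was not tested. MALAT1, an abundant nuclear RNA, was 2.96-fold higher, and its 3 probe sets differed by 1.40, 1.57 and 1.59. The 3 probe sets of LINC-PINT differed by 1.02, 1.45 and 1.56. The median over the 209 was 0.05, at the 98.9th percentile of matched random lists. Of 202 kept microRNA genes, 11 were higher and 13 lower, and their median of -0.07 was below those of all random lists. MIR21 went the other way, at 3.42-fold higher (5.09 and 6.86). Whether these probe sets read mature microRNAs or longer transcripts that hold them is not known here. HSPA6, a strictly stress-inducible heat shock gene outside the fixed lists, read 4.66 in the uncompressed culture, below the floor, and 6.17 in the compressed culture.

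The level filter hid some genes that were dim in 1 culture. Of 332 genes with a mean under the floor but the brighter array above it, 49 were at least 1.5-fold higher and 30 lower. They include MMP1 and CXCL8, the cholesterol gene HSD17B7 (3.42 in the uncompressed and 4.96 in the compressed culture) and ATF3, a stress-induced transcription factor gene (4.20 and 5.21). Their uncompressed levels lie below the floor, so no folds are given. A mean under the floor with 1 array above it requires a gap between the arrays. The counts of 49 and 30 are therefore raised by the selection itself.

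Several of the largest negative differences (ANXA13, VIL1, GPA33) are genes of intestinal epithelium. Lower expression of brush-border genes as a group is a hypothesis that an added list, without these genes, left undecided. Its 12 kept members had a median of -0.17 at the 1.07th percentile, short of the limit of 0.5. PLS1 was 1.51-fold lower and ANKS4B differed by -0.57, whereas ANPEP was 1.71-fold higher.

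Higher cholesterol biosynthesis genes might go with lower LXR activity, since LXR receptors respond to sterols. The 4 kept LXR targets had a median of -0.072, and 0 of 4 were 1.5-fold lower (MYLIP at -0.43, TMEM135 at 0.09), so 4 genes are too few to decide.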
